A study of Mus musculus with 2 samples.

How the data were processed

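RNA-seq was done on mouse haematopoietic stem and progenitor cells carrying the wild-type PML/RARa (WT) or the form labelled 2KR. Cells were exposed to concentrated lentivirus with 6 µg/ml polybrene by spinning at 1800 rpm for 40 min, then kept for 24 h before a change of medium. The medium held 50 ng/ml SCF, 10 ng/ml IL-3, 10 ng/ml IL-6 and 20% fetal bovine serum, per the labels' protocols. Grouping followed the infection stated for each sample, which gave 1 library per form.

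Per the submitters' processing notes, HISAT2 2.0.4 and the mouse build GRCm38 were used. The program that counted reads, the annotation release, the strandedness of the libraries and any removal of duplicates are not given in the sources used here. Per the file headers, the authors deposited for each library a raw read count and an FPKM value (fragments scaled to gene length and library total) for each of 34745 gene models, with the Ensembl identifier, the symbol and the coordinates. The deposited FPKM was equal, within 0.1%, to the count divided by a fixed gene length and by the library total in 15403 of 15403 models with counts in both libraries, so it holds no further normalization. Coordinates are those in the files. Identifiers were matched to GENCODE M21 on GRCm38 for strand and gene type; 34267 matched, and 27699 of these had an identical start and end. Where counting does not use strand, reads of overlapping or antisense models cannot be told apart, and reads of near-identical copies may be split or lost.

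The counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, with factors of 0.9931 for WT and 1.0070 for 2KR, and expressed as CPM. Later steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The log2 ratio is that of CPM + 1, 2KR over WT, which understates the difference of low genes. Gene models with a mean of at least 1 CPM were tested, and a model was counted as different when this log2 ratio was at least 1 in size. No test was run, since 1 library per form gives no replicate error. Folds in the text are ratios of CPM without the pseudocount. Their 95% intervals are exact Clopper-Pearson intervals of the count ratio given both scaled totals, and they cover counting error only. For a library with 0 counts the floor was 3 counts per library, which is 0.172 CPM in WT and 0.146 in 2KR. Bounds written as at least N-fold use this floor, close to a one-sided 95% limit; the two-sided interval has a lower limit of 229-fold for Mecom, 159-fold for RP23-325D10.3, 79.9-fold for Adgrd1 and 25.6-fold for Prss34. The medians of the lists that hold Mecom or Prss34 are the same with these genes at their bound, since each lies at the end of its list.

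The totals were 17606168 counts in WT and 20462011 in 2KR, and 13189 and 13287 models had at least 10 counts. The 50 most abundant models took 14.74% of WT counts (Wilson 95% interval 14.72 to 14.76) and 13.47% of 2KR counts (13.45 to 13.48). Counting error is known from these totals, and variation between cultures was not measured.

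The rule for named genes took the 12 genes with the largest and the 12 with the smallest log2 ratio among those at 5 CPM or more in the higher library. It added the 4 genes with the largest rise and the 4 with the largest fall in CPM. Models named Gm plus digits, ending in Rik or marked as pseudogenes, and rows with no symbol, were left out of both. From each described list it took up to 4 tested members with the largest size of log2 ratio and the 2 with the highest mean, and Pml and Rara were always named. Genes named outside this rule were chosen after their values were seen: Hdc, Fcer1g, Mcpt8, Ly6c2, Csf1r, Ier2, Cebpa, Gfi1, Elane, Cd34, Mycn, Meis1, Cd38, Ggnbp1, Hsd3b7, Ube2v1, Gm20431, Gm20716, Ctnna2, Mynn, Sec62 and Xist.

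For each of 35 gene lists, the median log2 ratio of the tested members was placed among 10000 random lists of the same size, matched over 20 bins of mean expression. Lists with fewer than 5 tested members give values only, which held for 2 lists. This percentile describes the libraries and is not a p-value. The lists, the rule for named genes, the 2-fold rule, the filter and the first set of alternatives were fixed before the data were examined.

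The size rule and the list percentiles were tested on simulated data, drawn as counting noise around the real levels for 12487 genes of the 2KR against WT comparison. The rule called 0 of 12288 unchanged genes. It recovered 17 of 50 genes made 2-fold different, 46 of 50 at 3-fold, 50 of 50 at 4-fold and 50 of 50 at 8-fold. A true 2-fold difference lies at the threshold of the rule. The counting interval held a ratio of 1 in 95.4% of unchanged genes, 24 of 400 random lists stood apart, and 20 of 20 lists shifted by 0.5 did. With an assumed biological coefficient of variation of 0.2, the rule called 145 of 12261 unchanged genes.

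Alternatives tried were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 CPM, ratios centred on their median, scaling without the 50 most abundant genes, size rules of 4-fold and 1.5-fold, leaving out models without a proper symbol, and 10 expression bins. Median-of-ratios size factors, the deposited FPKM in place of CPM, and the summing of overlapping models into 1 locus were added after the data were seen. Chaperone genes used in the closing tests were also listed at that stage.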

Results

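Gene expression was measured by RNA-seq in mouse haematopoietic stem and progenitor cells carrying either of 2 forms of PML/RARa. PML/RARa is the fusion of the nuclear body protein PML and the retinoic acid receptor alpha that drives acute promyelocytic leukaemia. Marrow cells of C57BL/6 mice pretreated with 5-fluorouracil were enriched for progenitors, transduced with lentivirus and grown in medium with SCF, IL-3 and IL-6, cytokines that favour myeloid growth. Transduced cells were then sorted. The labels give 1 library of the wild-type fusion (WT) and 1 library of the form labelled 2KR, and the series title states that 2 lysines of the fusion were studied. An arm with the empty vector is described in the protocol and was not analysed here. The WT library held 17606168 counts and the 2KR library 20462011, over the same 34745 gene models. A total of 16547 models in WT and 16498 in 2KR had at least 1 count.

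The question was which transcripts differ between cells with the 2KR form and cells with the wild-type fusion. Because each form had 1 library, no difference below has a replicate check, no p-value was computed, and the values describe these libraries only. Each fold, other than lower bounds, is given with an exact 95% interval of the ratio of counts, which covers counting error only.

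In cells with the 2KR form, 7 of 14 mast cell and basophil genes were at least 2-fold lower and 1, Mcpt8, was at least 2-fold higher. Of 20 immediate early genes 8 were at least 2-fold lower, Egr1 and Fos among them, and 2 had a ratio above 1. The lists of proliferation and ribosome genes had small shifts upward in their medians, with 0 members at least 2-fold higher. Of 16 primary granule genes 3 were at least 2-fold higher and 5 had a ratio below 1. Of 23 progenitor genes 5 were at least 2-fold higher and 7 had a ratio below 1, 1 of them at least 2-fold lower. Of 12466 gene models with a mean of at least 1 CPM (counts scaled to library size), 331 were at least 2-fold higher in 2KR and 569 were at least 2-fold lower. These 900 models were 7.22% of those tested, and 63.2% of them were lower in 2KR. At 4-fold, 52 were higher and 140 lower. For all 900 the counting interval of the ratio lay wholly beyond 1.5-fold, but the size rule had picked them from these same counts. The bulk of the transcriptome was close between the libraries: the median log2 ratio of 2KR over WT was 0.02, its quartiles were -0.21 and 0.23, and 83.41% of models lay within 1.5-fold.

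**Figure D1:**
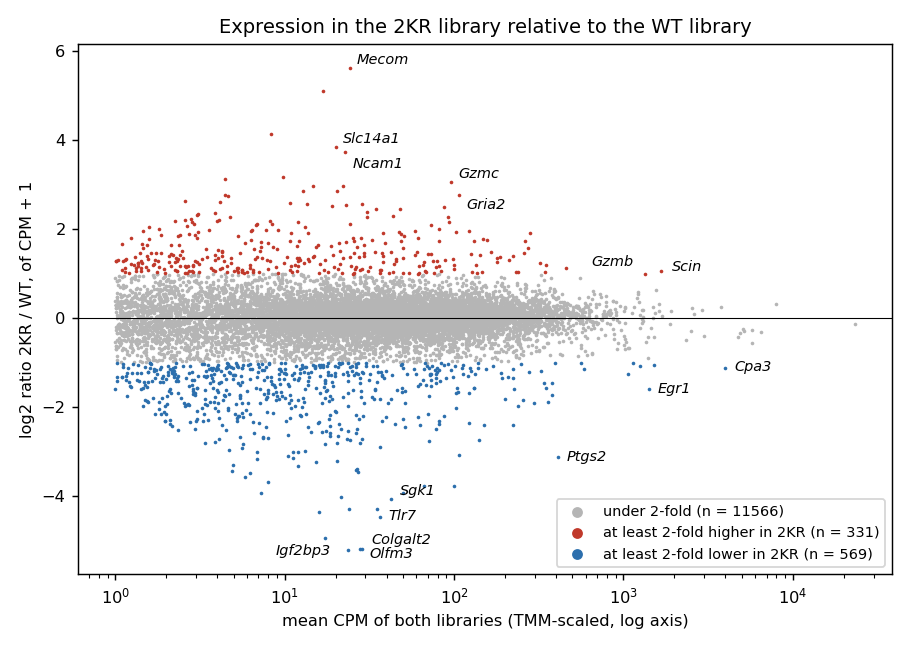
Each point is a gene model with a mean of at least 1 CPM; the x axis is the mean CPM of both libraries on a log axis and the y axis the log2 ratio of CPM + 1, 2KR over WT, with 1 library per form. Red points are the 331 models at least 2-fold higher in 2KR, blue points the 569 at least 2-fold lower, and grey points the rest, which gather around 0.

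The mouse gene models of the fusion partners were read at moderate levels. Pml (ENSMUSG00000036986, chromosome 9, 58218076 to 58249786 in GRCm38) had 53.2 CPM in WT and 72.2 in 2KR, a ratio of 1.36 (1.25 to 1.47). Rara (ENSMUSG00000037992, chromosome 11, 98927818 to 98974942) had 83.2 and 102.3 CPM, a ratio of 1.23 (1.15 to 1.31). The files hold no separate model for the fusion, and the species of its coding sequence is not given in the sources used here. These values may therefore hold reads of the introduced transcript, and they neither measure it nor check the labels. The list of PML body and SUMO pathway genes had a median log2 ratio of 0.09 over 22 genes, at percentile 85.1 of random lists matched on expression, and no member differed 2-fold.

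The gene with the largest log2 ratio was Mecom (ENSMUSG00000027684, chromosome 3, 29951296 to 30548008), which encodes a zinc finger transcription factor of haematopoietic stem cells. It had 0 counts in WT and 997 in 2KR, or 48.4 CPM, which is at least 282-fold higher when 3 counts are taken as the floor of the WT library. Slc14a1, a urea transporter, was 22.3-fold higher (15.5 to 33.3), and Ncam1, a neural cell adhesion molecule, was 18.8-fold higher (13.7 to 26.6), from 2.29 to 43.1 CPM. Gria2 (chromosome 3, 80681450 to 80802835), a glutamate receptor subunit, had 26.5 CPM in WT and 187 in 2KR, 7.06-fold higher (6.41 to 7.79). The potassium channel gene Kcnq5 had 2 and 181 counts, a ratio of 76.8 (20.95 to 639). Clstn3 was 16.0-fold (10.2 to 26.5), Enpp6 21.2-fold (10.1 to 53.5), Sh2d5 10.6-fold (7.79 to 14.8) and Dmxl2 9.87-fold higher (7.17 to 13.9). Zbtb9 was 9.49-fold higher (7.48 to 12.2) and RP23-325D10.3 had 0 and 692 counts, at least 196-fold higher. Both overlap another gene model that was lower in 2KR: Ggnbp1 had 648 and 118 counts beside Zbtb9, and Hsd3b7 had 915 and 455 beside RP23-325D10.3, so these 2 ratios are uncertain.

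The genes with the most negative log2 ratios had appreciable levels in WT and few counts in 2KR. Igf2bp3 (ENSMUSG00000029814, chromosome 6, 49085223 to 49214957), an RNA-binding protein of fetal tissues, had 47.1 CPM in WT and 0.291 in 2KR, 162-fold lower (74.0 to 442). Olfm3 and the collagen galactosyltransferase gene Colgalt2 were 104-fold (57.8 to 209) and 97.9-fold lower (55.8 to 190). Tgfb2, a ligand of the TGF-beta family, had 604 and 3 counts, a ratio of 237 (80.8 to 1154). Adgrd1, an adhesion G protein-coupled receptor gene, had 252 and 0 counts and was at least 99.0-fold lower. Tlr7 (chromosome X, 167304929 to 167330558), the endosomal sensor of single-stranded RNA, was 31.6-fold lower (23.6 to 43.5), and Il7r, the interleukin 7 receptor alpha chain, was 53.8-fold lower (30.6 to 105). Sgk1, a kinase gene induced by glucocorticoids, was at 80.4 CPM in WT and 3.88 in 2KR, 20.7-fold lower (16.5 to 26.3). Cntn1 was 33.1-fold (22.9 to 49.7), Pax6 27.2-fold (20.6 to 36.8), Nav2 25.7-fold (18.2 to 37.7) and Coch 18.0-fold lower (14.8 to 22.1).

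In absolute level, the largest differences were in abundant transcripts. Eef1a1, the translation elongation factor, had 7098 CPM in WT and 8870 in 2KR, a ratio of 1.25 (1.24 to 1.26). Scin, an actin-severing protein, was 2.08-fold higher (2.05 to 2.12), from 1082 to 2255 CPM. Gzmb (ENSMUSG00000015437, chromosome 14, 56258856 to 56262260), the serine protease granzyme B, was 2.00-fold higher (1.97 to 2.04), from 897 to 1798 CPM. Calr, an endoplasmic reticulum chaperone, was 1.54-fold higher (1.52 to 1.57). In the other direction, Cpa3 (ENSMUSG00000001865, chromosome 3, 20215620 to 20242181), the mast cell carboxypeptidase, had 5468 CPM in WT and 2525 in 2KR, 2.17-fold lower (2.14 to 2.19). The mitochondrial transcripts mt-Co1 and mt-Cytb were 1.10-fold (1.098 to 1.11) and 1.48-fold lower (1.47 to 1.496). Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), a transcription factor induced within minutes of receptor stimulation, was 3.03-fold lower (2.97 to 3.09), from 2120 to 699 CPM.

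Gene lists fixed before the data were examined were compared with random lists matched on expression. A list was said to stand apart when its median log2 ratio lay in the lowest or highest 2.5% of 10000 random medians. Of 33 lists with at least 5 tested genes, 8 stood apart on the lower side and 11 on the higher side, 19 in all. Lists of randomly drawn genes would give 1.7. Genes of a real list can move together in any difference between 2 cultures, so this excess is a description and not a test. After genes held by more than 1 list were left out, 18 of the 19 still stood apart.

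Mast cell and basophil genes had the lowest median, -0.93 over 14 tested genes, lower than all 10000 random medians. Of the 14, 12 had a ratio below 1, 7 were at least 2-fold lower and 1 was at least 2-fold higher. Hdc, the histamine-producing enzyme, was 2.02-fold lower (1.96 to 2.07). Fcer1g, the gamma chain of the IgE receptor, was 1.80-fold lower (1.75 to 1.85), and Il1rl1, the interleukin 33 receptor, was 2.23-fold lower (2.11 to 2.36). Mitf, a transcription factor of mast cells, was 5.78-fold lower (4.27 to 7.95), and Ms4a2, the IgE receptor beta chain, was 4.32-fold lower (2.54 to 7.73). The mast cell chymase gene Cma1 had 62 and 2 counts, and the basophil protease gene Prss34 had 82 and 0 counts, at least 32.2-fold lower. The member on the other side was Mcpt8, a basophil protease gene, which was 2.37-fold higher in 2KR (2.27 to 2.46), from 190 to 450 CPM.

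Monocyte and macrophage genes had a median of -0.43 over 14 genes, at percentile 0.08, with 8 ratios below 1 and 6 above, and 5 at least 2-fold lower and 1 higher. Gpnmb (chromosome 6, 49036546 to 49070929), a glycoprotein of macrophages, was 13.6-fold lower (10.8 to 17.5). It lies near Igf2bp3, which was also far lower in 2KR, and a cause local to this region was not tested. The transcription factor gene Klf4 was 7.90-fold lower (5.36 to 12.01), and the chemokine receptor genes Cx3cr1 and Ccr2 were 4.89-fold (4.40 to 5.45) and 2.10-fold lower (1.96 to 2.26). Ly6c2, a surface marker of monocytes, was 7.35-fold higher (4.30 to 13.5), from 15 to 130 counts. With no filter on low values the list's median was -0.002, at percentile 53.88. Csf1r, the receptor of macrophage colony-stimulating factor, had 10 and 12 counts.

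The list of immediate early genes, which are induced rapidly, had a median of -0.77 over 20 genes, below all 10000 random medians, with 8 genes at least 2-fold lower and 0 at least 2-fold higher, and for 18 of the 20 the counting interval lay wholly below 1. Egr3 was 13.5-fold lower (10.6 to 17.3), Fosb 13.9-fold (8.21 to 25.4), Nr4a1 7.13-fold (6.37 to 7.99), Fos 5.14-fold (4.68 to 5.65) and Zfp36, an mRNA decay factor, 3.74-fold (3.59 to 3.90). The inflammatory list had a median of -0.67 over 17 genes, also below all random medians, with 14 ratios below 1, and 4 genes at least 2-fold lower and 1 higher. In it Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), the inducible cyclooxygenase, had 738 CPM in WT and 83.3 in 2KR, 8.86-fold lower (8.42 to 9.32). The chemokine gene Ccl6 was 3.95-fold lower (3.18 to 4.95), and Cxcl3, on the other side, was 2.39-fold higher (1.80 to 3.21). Feedback genes of MAPK and STAT signalling had a median of -0.40 over 22 genes, below all random medians, with 17 ratios below 1 and 5 above. Of these genes, 2 were at least 2-fold lower, Cish by 2.99-fold (2.81 to 3.19) and Spry1 by 2.40-fold (2.08 to 2.78). The cyclin gene Ccnd1 was higher, with 6 and 44 counts. The list of cytokine and growth factor receptors had a median of -0.13 over 18 genes at percentile 2.99, just short of standing apart, and Il1rl1 was its only 2-fold difference.

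**Figure D2:**
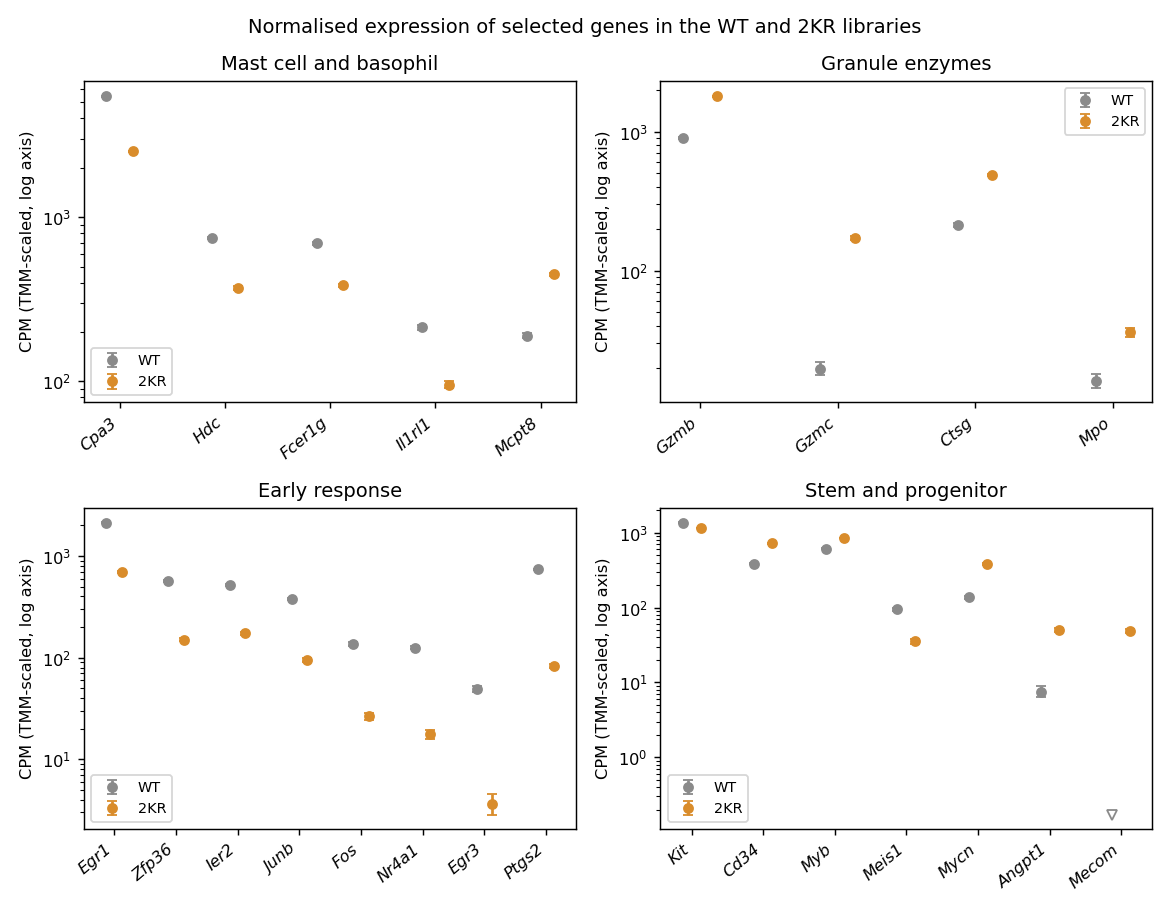
Points are TMM-scaled CPM on a log axis for named genes in the WT library (grey) and the 2KR library (orange), 1 library per form, with bars for the 95% Poisson counting interval. The open triangle marks Mecom in WT, which had 0 counts and is drawn at the floor of 3 counts, 0.172 CPM. Of the genes drawn, the mast cell genes other than Mcpt8 and all 8 early response genes were lower in 2KR. The 4 granule enzyme genes drawn were higher, and Ctsg, Gzmc and Gzmb lie near each other on chromosome 14. The genes drawn are a selection and not whole lists, and Gzmb and Gzmc are not in the primary granule list. In the full lists, 5 of 16 primary granule genes had a ratio below 1 and 2 of 20 immediate early genes a ratio above 1.

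Myeloid transcription factors had a median of -0.61 over 19 genes, below all random medians, with 12 ratios below 1 and 7 above, 6 at least 2-fold lower and 0 higher. Cebpd and Cebpb, regulators of the inflammatory and late myeloid programme, were 5.91-fold (4.87 to 7.23) and 3.92-fold lower (2.97 to 5.23), and Junb was 3.98-fold lower (3.79 to 4.19). In the opposite direction Cebpa and Gfi1, regulators of granulocyte commitment, were 1.63-fold (1.499 to 1.78) and 1.52-fold higher (1.41 to 1.63), under the 2-fold rule. Of the 19, 13 also belonged to other lists, and without them the median was -0.48 at percentile 0.95.

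The primary granule list stood apart on the higher side, with a median of 0.45 over 16 genes, above all 10000 random medians. Of the 16, 11 had a ratio above 1 and 5 below, 4 of these with the counting interval wholly below 1, and 13 differed less than 2-fold. The 3 at least 2-fold higher were Hk3, a hexokinase of myeloid cells, at 3.95-fold (3.67 to 4.26), Ctsg, the protease cathepsin G, at 2.29-fold (2.21 to 2.38), and Mpo, myeloperoxidase, at 2.22-fold (1.93 to 2.56). Mpo was low in both libraries, at 16.2 and 36.0 CPM, and Elane, neutrophil elastase, had 5 and 10 counts. Gzmc (ENSMUSG00000079186, chromosome 14, 56231401 to 56234656), a granzyme gene near Gzmb, was 8.73-fold higher (7.81 to 9.78), from 19.7 to 172 CPM. Ctsg (chromosome 14, 56099881 to 56102574) lies near both. Cma1, which was lower in 2KR, lies in the same region (55941453 to 55944661). A cause local to this region was not tested. Late granulocyte genes did not stand apart, with a median of -0.14 over 9 genes at percentile 13.5 and 0 differing 2-fold.

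Stem and early progenitor genes had a median of 0.18 over 23 genes at percentile 98.1, with 16 ratios above 1 and 7 below, and 5 at least 2-fold higher and 1 lower. Besides Mecom, the higher ones were Angpt1, a ligand of the receptor Tek, at 6.60-fold (5.50 to 7.97), Egfl7 at 3.53-fold (3.07 to 4.06), Lmo2 at 3.33-fold (2.72 to 4.09) and Mycn at 2.77-fold (2.65 to 2.91). Meis1, a homeobox factor of stem cells, was 2.67-fold lower (2.45 to 2.92). The progenitor antigen gene Cd34 was 1.86-fold higher (1.81 to 1.92), from 388 to 723 CPM, while Kit was 1.17-fold lower (1.15 to 1.19), from 1359 to 1159 CPM. This list did not stand apart once genes shared with other lists were left out, at percentile 97.48, with a pseudocount of 5, with a mean of at least 5 CPM, or on FPKM.

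Genes of growth and proliferation had small ratios, most of them above 1. The list of MYC targets and ribosome biogenesis had a median of 0.39 over 24 genes, and 23 of them had a ratio above 1. Nop56 was 1.52-fold (1.43 to 1.62), Cdk4 1.48-fold (1.42 to 1.53) and Npm1 1.46-fold higher (1.43 to 1.501). DNA replication genes had a median of 0.37 over 26 genes, with 24 ratios above 1, among them Prim1 at 1.54-fold (1.43 to 1.67). The other 2 genes of this list had the counting interval wholly below 1, with Fen1, the flap endonuclease, 3.67-fold lower (3.27 to 4.14). Mitosis genes had a median of 0.28, with all 25 ratios above 1, for example Top2a at 1.29-fold (1.26 to 1.32). These 3 medians lay above all random medians. Cytosolic ribosomal protein genes had a median of 0.24 over 40 genes at percentile 99.99, with 38 ratios above 1. Genes of double-strand break repair had a median of 0.20 over 20 genes at percentile 99.1, with 18 ratios above 1 and Brca2 1.76-fold higher (1.58 to 1.96). Targets of p53 had a median of 0.36 over 20 genes, above all random medians, with 16 ratios above 1 and 4 below, 3 of these with the counting interval wholly below 1. Among them Zmat3 was 1.96-fold (1.84 to 2.09) and Cdkn1a, a cell cycle inhibitor, 1.56-fold higher (1.51 to 1.61), while the death receptor gene Fas was 2.21-fold lower (1.59 to 3.11) and stayed under the size rule because of the pseudocount. Over these 6 lists, Fen1 was the only 2-fold difference under the size rule.

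Mitochondrially encoded mRNAs had a median of -0.31 over 13 genes at percentile 0.095, with 0 differing 2-fold, and 12 of the 13 had a ratio below 1. All models on the mitochondrial chromosome, not only these mRNAs, took 7.45% of WT counts (Wilson interval 7.44 to 7.46) and 6.22% of 2KR counts (6.21 to 6.23). Nuclear genes of oxidative phosphorylation did not stand apart, with a median of 0.09 over 24 genes at percentile 84.6. Glycolysis and hypoxia genes had a median of -0.13 over 25 genes at percentile 0.815, with 16 ratios below 1 and 9 above, 7 of these with the counting interval wholly above 1. Pfkp was 2.28-fold lower (2.12 to 2.44), the only member past 2-fold, and Ndrg1 was 1.74-fold lower (1.70 to 1.79). The abundant members Ldha and Pkm were 1.18-fold (1.16 to 1.21) and 1.12-fold higher (1.098 to 1.13).

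Markers of other lineages gave mixed values. Erythroid genes had a median of 0.32 over 10 genes at percentile 98.9 and a mean of 0.06, with 7 ratios above 1 and 3 below. Of them, Hemgn was 3.46-fold (3.25 to 3.70) and Car2 3.80-fold higher (3.02 to 4.84), and Aqp1 was 5.80-fold (5.25 to 6.42) and Sphk1 7.78-fold lower (3.97 to 17.0). With no filter on low values the erythroid median was 0.001 at percentile 50.79. Lymphoid genes had a median of 0.46 over 6 genes at percentile 99.2 but a mean of -0.10, with 3 ratios above 1 and 3 below, 2 of these with the counting interval wholly below 1. The median is thus the midpoint of members on both sides, and Il7r was the lowest. Dntt, the terminal transferase, was 4.95-fold (4.52 to 5.43), the kinase gene Lck 2.81-fold (2.26 to 3.50) and Thy1 2.07-fold higher (1.98 to 2.17). With no filter the lymphoid median was 0.063 at percentile 82.14. Genes of stroma and endothelium had a median of 0.53 over 8 genes at percentile 99.8, with 6 ratios above 1 and 2 below, led by Bgn at 4.24-fold (2.996 to 6.15), from 2.23 to 9.46 CPM. Megakaryocyte genes did not stand apart, with a median of 0.20 over 9 genes at percentile 92.9, and with 5 ratios above 1 and 4 below, 3 of these with the counting interval wholly below 1. Pf4, platelet factor 4, was 3.35-fold (3.19 to 3.52) and Ppbp 2.64-fold higher (2.21 to 3.16), while Itgb3, the abundant integrin beta chain, was 1.63-fold lower (1.596 to 1.67), from 1130 to 693 CPM. Itga2b, an integrin of megakaryocytes, was at 867 and 858 CPM. The eosinophil list had 2 tested genes, Il5ra at 43 and 15 counts and Siglecf at 10 and 39.

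Genes of the retinoic acid response, the pathway of the receptor part of the fusion, did not stand apart. Their median was 0.13 over 9 genes at percentile 81.1, with 3 at least 2-fold higher and 2 lower. Icam1 was 4.30-fold (3.42 to 5.45), Cd38 2.81-fold (1.79 to 4.54) and Dhrs3, a retinaldehyde reductase, 2.47-fold higher (1.99 to 3.07), while Cebpb and the transglutaminase gene Tgm2 were 3.92-fold (2.97 to 5.23) and 2.69-fold lower (2.12 to 3.42). Corepressor and chromatin genes had a median of 0.07 over 20 genes at percentile 77.6. Dnmt3b, a de novo DNA methyltransferase, was the only member past 2-fold, at 3.38-fold higher (3.10 to 3.69).

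**Figure D3:**
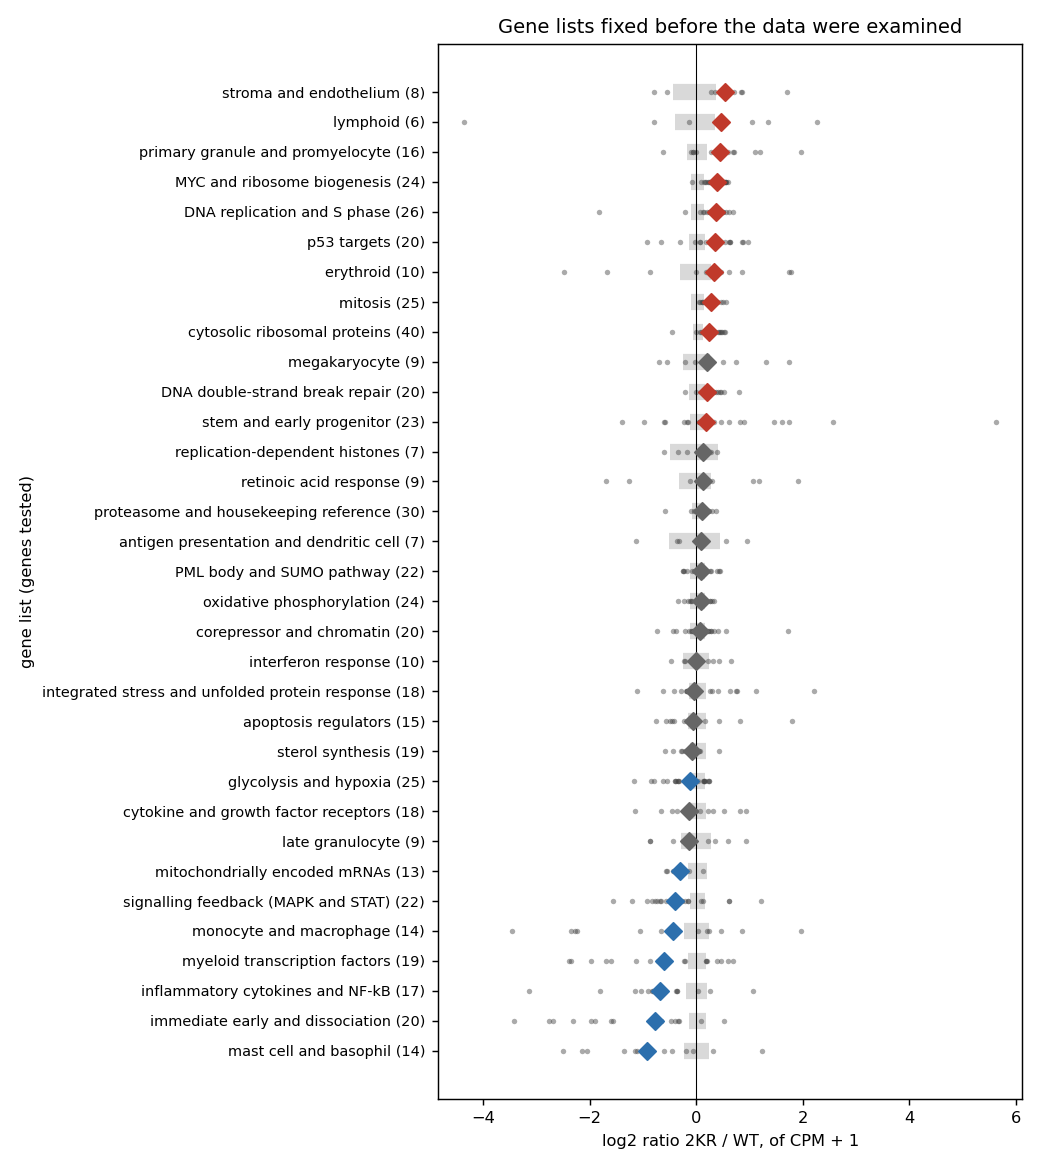
Each row is a gene list with its number of tested genes; dark points are genes, the diamond is the list median, and the x axis is the log2 ratio of CPM + 1, 2KR over WT. Grey bars span the middle 95% of medians of 10000 random lists matched on expression. Blue and red diamonds are the 8 lists that stood apart on the lower side and the 11 on the higher side, and grey diamonds the rest.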

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

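Median-of-ratios scaling, the deposited FPKM and the summed loci were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because each form had 1 library, and for the same reason no library could be left out. Against 331 models higher and 569 lower in the main setting, a pseudocount of 5 gave 147 and 297, a mean of at least 5 CPM 207 and 377, a 4-fold rule 52 and 140, a 1.5-fold rule 863 and 1205, and the deposited FPKM 153 and 263. The pseudocount, the filter and the size rule act on these counts by their construction. The other 7 settings stayed within 1.5 times the main counts for both directions, among them no filter with 349 and 601, median-of-ratios scaling with 325 and 572, and overlapping models summed with 268 and 496. The share of lower calls lay between 58.3% and 72.9% over the settings with gene models, and the scalings moved it by less than 10 percentage points. Of the lists, stem and early progenitor had a median of 0.146 (percentile 97.08) with a pseudocount of 5, 0.143 (95.21) with a mean of at least 5 CPM and 0.152 (93.10) on FPKM, and so no longer stood apart. Erythroid genes had 0.146 (93.55) with a pseudocount of 5 and 0.001 (50.79) with no filter. With no filter, monocyte and macrophage genes had -0.002 (53.88) and lymphoid genes 0.063 (82.14). In that setting members with few reads also enter, and the pseudocount draws their log2 ratios toward 0. Receptor genes stood apart with -0.122 (2.47) at a pseudocount of 5, -0.139 (2.18) at a mean of at least 5 CPM and -0.100 (2.39) on FPKM, and megakaryocyte genes did with 0.378 (99.82) on FPKM. The cause was not tested except where stated. The remaining 281 values of lists kept their side. Of the values of named genes 113 moved beyond their counting interval and 1521 did not, and 0 values were reversed. On depth, all 900 calls had a counting interval wholly beyond 1.5-fold, but the size rule picked them, and in simulated counts it recovered 17 of 50 true 2-fold differences. Variation between cultures was not measured.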

Other observations

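The tests of overlapping models, of genes read in 1 library and of immediate early genes were chosen after those results had been seen. Several lists that the comparison above leaves out did not stand apart. Interferon response genes had a median log2 ratio of -0.0005 over 10 genes at percentile 48.0, with 0 differing 2-fold, although Tlr7 was far lower in 2KR. Antigen presentation genes had a median of 0.09 over 7 genes at percentile 68.1 and a mean of -0.01, sterol synthesis genes -0.09 over 19 genes at percentile 6.39, and replication-dependent histone genes 0.13 over 7 genes at percentile 72.4 with a mean of -0.02. Proteasome and housekeeping genes had 0.12 over 30 genes at percentile 96.0.

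Apoptosis regulators had a median of -0.06 over 15 genes at percentile 16.9, with Xiap, an inhibitor of caspases, 3.56-fold higher in 2KR (3.22 to 3.94) and Bcl2 1.48-fold lower (1.43 to 1.53). Genes of the integrated stress and unfolded protein responses had a median of -0.04 over 18 genes at percentile 21.2 and a mean of 0.18. In that list Asns, asparagine synthetase, was 9.21-fold (5.32 to 17.3) and Chac1 2.80-fold higher (1.89 to 4.23), while Ppp1r15a was 2.19-fold lower (2.05 to 2.33). Of the sex-linked list, Ddx3y was at 96.8 and 103.6 CPM and Xist at 4 and 1 counts. The neighbours of Mecom, Mynn and Sec62, had 430 and 1983 counts in WT and 449 and 2219 in 2KR. These counts do not decide whether the cause is local to Mecom, and reads across vector junctions were not analysed here. Chromosome medians lay between -0.01 and 0.05 over 20 chromosomes, and groups of genes by length had medians from 0.04 for the shortest to -0.01 for the longest.

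The first pattern concerns gene models that overlap: of 13 overlapping pairs in which both models differed at least 2-fold in opposite directions, 11 were under 2-fold once their counts were summed. Pairs picked for opposite directions move toward 1 when summed whatever the cause, and 12 of 25 such pairs of adjacent models that do not overlap were also under 2-fold. The 13 pairs are not independent, since several combine Pcdhg models of the same locus on chromosome 18 and Gm20708 is in more than 1. Ube2v1 had 717 and 110 counts and Gm20431 573 and 1394, with a sum of 1290 in WT and 1504 in 2KR. Whether reads of 1 transcript were assigned to different models in each library, or the cells switched promoter or isoform, stays open. Reads swapped between overlapping tested models do not account for the comparison as a whole, since 747 of the 900 calls overlapped no other tested model. Overlap with models under a mean of 1 CPM was not counted.

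The second pattern is a set of 11 genes with at most 3 counts in 1 library and at least 100 in the other, 5 read in 2KR, Mecom among them, and 6 in WT. Reads assigned to an overlapping model instead are argued against for 9 of them: 6 overlapped no model with reads, and the models over the other 3 (Tgfb2, Ctnna2 and Mecom) held 0 reads in the library where the gene was near 0. For Gm20716 and RP23-325D10.3 this stays open. The models over these 2 held 3946 and 4650 reads in WT, more than the 341 and 692 of the genes in 2KR. In 2KR those models held 4512 and 4746 reads, counts not scaled to the larger total of that library. Whether they fell, after scaling, by the reads gained was not tested. Stem cells present in the 2KR library alone stay open for Mecom: 7 stem cell genes with at most 10 reads in WT had 12 reads in all in 2KR beside its 997, but genes near the floor exclude nothing, and the stem list went both ways, with Angpt1, Egfl7 and Lmo2 higher in 2KR and Meis1, Kit and 5 others lower. Cultures grown from few founder cells might differ in this way, and 5 of 12 variable Pcdhg models differed at least 2-fold (41.7%, against 469 of 3136 genes of like expression), but these models share exons, so this stays open.

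The third pattern is the lower level of immediate early genes in 2KR. Handling stress of the WT cells that also raised heat-shock chaperones would give these a negative median. The median log2 ratio of 14 chaperones, 2 of them also in the immediate early list, was 0.181, with quartiles of 0.05 and 0.35, on the opposite side. Handling that raised immediate early genes without chaperones was not tested by this and stays open. Weaker receptor and MAPK signalling in the 2KR cells stays open: the feedback list had a median of -0.403, but this value was known before the hypothesis was set and does not test it. In that list 17 of 22 genes were below 0 and 5 above, among them Ccnd1, Ccnd2 and Pim2, and the lists of MYC targets and proliferation stood apart on the higher side. With 1 library per form, an effect of the 2KR form and a difference in the culture or the time since feeding were not separated.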
